A study of Mus musculus with 8 samples.

How the data were processed

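Single enteroendocrine cells positive for a hormone reporter were sorted from mouse intestinal organoids (C57BL/6) into 384-well plates with spike-in RNA and processed by SORT-seq, a form of CEL-seq2 that tags each transcript with a molecular identifier, per the labels' protocols. Sequencing was paired-end at 75 bases on a NextSeq500, per the labels' protocols. Reads were aligned with BWA 0.6.2-r126 to mm10, per the submitters' processing notes. The counting tool, its annotation and its use of strand are not given in the sources used here. The 8 samples are 8 plates. On 5 of them the conditions lie in column blocks (columns 1 to 6 untreated, 7 to 12 24 h of BMP4, 13 to 24 4 days), and the deposited well list matches the labels in 1920 of 1920 wells. All samples share one source name, so the labels give no batch.

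The deposited values are expected counts per gene and well: transcript numbers that the authors corrected for identifiers hit more than once. Inverting that correction with 4096 possible identifiers, the number of 6-base ones, gave whole identifier counts, within 0.01, for 100.0% of nonzero values on each plate, whereas the labels state identifiers of 4 bases, of which 256 exist. The deposited expected counts were rounded to whole numbers after summing, before any count test. Files of 5 plates, all of the Tac1 line, hold values rounded to 2 decimals and include mitochondrial genes. Files of 3 plates, of the Gip and Gcg lines, hold full precision and list no mitochondrial gene. Only the 16115 genes listed in at least one file of each kind were used, out of 17124 and 19754. The others hold 1.34 to 2.05% of transcripts per plate. Spike-ins and mitochondrial genes stayed out of totals. Gene symbols are those of the files. Of the 16115, 95.7% are in GENCODE M21 of the same assembly, and 15415 of 15422 matched symbols lie on the chromosome that the files give.

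Cells with at least 2000 transcripts were kept (1006 of 3072 wells) and summed per plate and condition. A sum needed at least 10 cells, which left 14 sums. No doublet caller was run, because each well received one sorted cell. Genes were filtered with edgeR's filterByExpr, normalised with TMM and tested with edgeR's quasi-likelihood F test (edgeR 4.0.16, R 4.3.3), with plate as a block and condition as a term, or condition within reporter line. P-values were adjusted by Benjamini-Hochberg and a gene passed under 0.05. Log2 changes are given with the standard error of the fit. Fits of the Tac1 and Gcg lines share one estimate of the spread with the Gip plate, which has no test of its own. Plates pair the conditions by design, and the residuals of sums from one plate correlated at 0.34 to 0.69 in all 13 pairs. Levels are CPM, the count of a gene in a sum scaled to a fixed total, with exact Poisson 95% intervals and a floor of 3 counts. Shares of cells have Wilson 95% intervals. Both cover counting error only.

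The design, the alternatives, the rule for named genes and 21 gene lists were fixed before the data were examined. Named genes per pooled comparison are the 8 largest rises and 8 largest falls among genes that passed with an average log2 CPM of at least 5 and one sign on every plate (predicted genes, Rik clones and ribosomal protein genes left out), every tested hormone and BMP target, and up to 4 genes per other list by smallest p. Per line they are the 5 largest each way and the hormones. Nt5e on the Gcg plates at 24 h falls outside this rule and was named after its values were seen, because it completes a short list. Fam101a also passed at 24 h over all plates, at 3.94, outside the rule. The lists hold hormones, BMP targets, BMP receptors and Smads, enteroendocrine transcription factors, secretory granule genes, serotonin genes, L, K and I cell genes, nutrient and hormone receptors, crypt and stem cell genes, Wnt targets, proliferation, enterocyte, villus tip, goblet, Paneth and tuft cell genes, immediate early and heat shock genes, the unfolded protein response, cholesterol synthesis, interferon and antigen presentation, and nuclear RNA quality. The result of 1 enterocyte gene, and the 4 day count over that list alone, are not reported here. The 18 lists with at least 2 tested genes were tested with camera (limma 3.58.1) on voom values at a preset correlation of 0.01. Among lists that did not pass, the mean or median differed in sign from camera's direction for serotonin (mean -0.10), villus tip (mean 0.15), immediate early and interferon genes at 24 h, and for granule (mean 0.03) and immediate early genes at 4 days.

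Cells were clustered with Leiden (scanpy 1.11.5, leidenalg 0.10.2; 1500 variable genes, 20 components, 15 neighbours, resolution 1.0) without the hormone and BMP target lists. The rule for a name was at least 3 fixed markers among the top 20 genes of a cluster. Enteroendocrine clusters of 81 and 93 cells, nearly all from Gcg plates, held only 1 and 2, so they took the name outside this rule. Results over enteroendocrine clusters alone include them. The naming thresholds were set after seeing the data, and clusters without a name are given as such. Enteroendocrine clusters held 800 cells (median 5940 transcripts), enterocyte-like 62 (16693), goblet-like 23 (8565) and unnamed 121 (3687). For shares of cells with a hormone, every cell was thinned to 2000 transcripts. Shares were compared within plates by an exact sign-flip permutation test, two-sided, whose smallest p is 0.0625 with 5 plates and 0.125 with 4.

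Simulated counts gave each gene one mean over all sums, with no difference between plates or lines. The rates below therefore do not cover genes whose level differs between them. The test was checked on a single such draw per comparison, with 200 changed genes. It recovered 29% of 2-fold and 91% of 4-fold changes in the pooled 24 h comparison (7990 genes; 4.76% of calls wrong), 27% and 93% at 4 days (8040 genes; 6.25% wrong), 10% and 80% on Gcg plates at 24 h (7949 genes; 14.3% wrong), 4% and 58% at 4 days (7944 genes; 11.4% wrong), 0% and 7% on Tac1 plates at 24 h (7864 genes; 22.2% wrong) and 0% and 13% at 4 days (7845 genes; 0% wrong).

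The alternatives were DESeq2 1.42.0, size factors by relative log expression, normalisation without hormones, no expression filter, cells with at least 1000 or 4000 transcripts, enteroendocrine clusters alone, equal cell numbers per condition, identifiers before the collision correction, reporter line in place of the plate block, all 5 Tac1 plates without the block, an estimated correlation for lists, cluster resolutions of 0.5 and 1.5, other thinning, and leaving out each plate. Sums of at least 5 cells, enteroendocrine clusters with sums of at least 5 cells, and leaving out the unnamed clusters were added after seeing the data. The 3 plates of a single condition enter no main test, because plate and condition coincide on them.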

Results

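Enteroendocrine cells, the scattered hormone-secreting cells of the gut epithelium, were sorted one by one from mouse intestinal organoids of 3 reporter lines. The lines carry a reporter for Tac1 (the substance P precursor of serotonin-making enterochromaffin cells), Gcg (proglucagon, the GLP-1 precursor of L cells) or Gip (the incretin hormone of K cells). By the sample titles those for Tac1 and Gip are Cre lines, whose label can stay in cells that no longer use the gene, and that for Gcg is a Venus line. Organoids had received no BMP4, BMP4 for 24 h or BMP4 for 4 days, and transcripts were counted per cell with molecular identifiers. BMP4 is a secreted ligand of the bone morphogenetic protein pathway, whose activity is known to be higher toward the villus than in the crypt. On 5 plates of 384 wells, all 3 conditions lay side by side: 2 plates of the Tac1 line, 2 of the Gcg line and 1 of the Gip line. A further 3 plates of the Tac1 line held a single condition each, 1 of 24 h and 2 of 4 days.

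Of 3072 wells, 1006 held at least 2000 transcripts, and 883 of these lay on the 5 plates with all conditions. The kept cells numbered 163 on Tac1 plate 1 (1028058 transcripts), 41 on Tac1 plate 2 (272191), 229 on Gcg plate 1 (2934214), 182 on Gcg plate 2 (2120486) and 268 on the Gip plate (2030540). The plates of a single condition held 48 cells at 24 h (195449 transcripts), and 30 and 45 cells at 4 days (99864.8 and 150923 transcripts). Median transcripts per cell on the 5 plates were 6517 without BMP4, 8543 at 24 h and 5177 at 4 days. On Tac1 plate 1, 70.8% of untreated wells and 21.4% of 4 day wells were kept. The values were 78.1% and 12.5% on Gcg plate 2, and 65.6% and 70.3% on the Gip plate. Gene tests compared sums over the cells of one plate and condition, which ranged from 104241 to 1251615 transcripts, so the plate is the replicate and n counts plates. Levels are in CPM, the transcripts of a gene scaled to a fixed total per sum. The 24 h wells of Tac1 plate 2 held 9 cells and gave no sum, which leaves 4 plates for comparisons with 24 h and 5 for 4 days against none. Nothing in the labels says that plates came from separate cultures, so p-values measure only the spread between plates, which may be technical. Untreated cells always filled columns 1 to 6, and 4 day cells columns 13 to 24, so condition and place on the plate coincide on the 5 plates.

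The first comparison, 24 h of BMP4 against none, asks what the ligand does early. Id1, Id2 and Id3, which encode inhibitors of helix-loop-helix transcription factors and are direct targets of BMP-activated Smads, rose on 4 of 4 plates by 4.76 ± 0.35, 3.50 ± 0.26 and 4.38 ± 0.25 on the log2 scale (SE, n = 4 plates; adjusted p = 3.5e-06, 3.5e-06 and 2.9e-07). Sct, which encodes the hormone secretin, rose by 3.18 ± 0.37 (adjusted p = 7.5e-04), from 1519 to 16848 CPM on Gcg plate 1 and from 323 to 2734 on Tac1 plate 1. Tbx3, a T-box repressor, rose by 2.69 ± 0.33 (adjusted p = 0.0015), and Sstr1, a somatostatin receptor, by 2.24 ± 0.29 (adjusted p = 0.0019), also on 4 of 4 plates.

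In all, edgeR's quasi-likelihood test called 8 of 8308 genes, 8 higher and 0 lower. In edgeR 214 had an unadjusted p under 0.05, and DESeq2 called 18. Of 8 tested BMP target genes, 4 rose and 4 did not pass (6 rose when adjusted over the list alone), and the list as a set lay above other genes (camera adjusted p = 2.0e-20; adjusted p = 0.0013 with an estimated correlation). The fourth was Smad6, an inhibitory Smad, at 3.38 ± 0.58 (adjusted p = 0.040). Smad7, its sister gene, was at 2.73 ± 0.62 (adjusted p = 0.32), and Skil, Bambi and Tgif1 at 0.85, -0.18 and 0.13. The call of Smad6 ended without any one of the 5 plates: the adjusted p was 0.062 without Gcg plate 1, 0.15 without Gcg plate 2, 0.59 without the Gip plate, 0.14 without Tac1 plate 1 and 0.087 without Tac1 plate 2 (5.1e-05 to 0.59 over its 18 alternatives). Of 12 hormones, Sct rose and 11 did not pass (2 rose when adjusted over the list alone). Pyy, which encodes peptide YY, was at 2.94 ± 0.70 (adjusted p = 0.35), Tac1 at -1.15 ± 0.49 and Gcg at -1.07 ± 0.84.

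Among goblet cell genes, none of 8 passed over all genes (edgeR; 1 higher and 4 lower when adjusted over the list alone), and the list lay below other genes (camera adjusted p = 3.1e-06; adjusted p = 0.19 with an estimated correlation). The mucin gene Muc2 was at -2.65 ± 0.49 (adjusted p = 0.069) and Fcgbp, a mucus protein gene, at -1.90 ± 0.44 (adjusted p = 0.32), while Clca1, another mucus protein gene, was at 2.23 ± 0.59. Goblet-like cells made up 2.56% of untreated and 1.67% of 24 h cells on average. The lists of the unfolded protein response (11 genes tested) and of enterocytes (14) also lay below other genes, with camera adjusted p = 0.0039 and 0.041. With an estimated correlation the adjusted p was 0.45 and 0.63. No member of either passed alone.

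The second comparison, 4 days of BMP4 against none, asks what a lasting signal does to hormones and cell identity. Sct rose on 5 of 5 plates by 4.10 ± 0.36 on the log2 scale (SE, n = 5 plates; adjusted p = 1.4e-05), reaching 15867 and 32251 CPM on the Gcg plates from 1519 and 2053. Pyy rose by 3.57 ± 0.73 (adjusted p = 0.012), and Nts, which encodes neurotensin, by 3.26 ± 0.68 (adjusted p = 0.021) on the 3 plates of the Gcg and Gip lines. Both Tac1 plates held 0 Nts transcripts in either condition. On the Gip plate few cells held Nts: of 216 thinned enteroendocrine cells of all conditions, 6 held any and 2 at least 5 transcripts. Tac1 fell by 2.13 ± 0.50 (adjusted p = 0.027) on 5 of 5 plates, from 2568 to 315 CPM on Tac1 plate 1 and from 3175 to 428 on Tac1 plate 2. Its fall on the Gcg and Gip plates rests on few cells: 4 of 294 and 9 of 216 thinned enteroendocrine cells held any Tac1. Iapp, the amylin gene, fell by 2.71 ± 0.42 (adjusted p = 0.0034) on 4 of 5 plates.

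**Figure D1:**
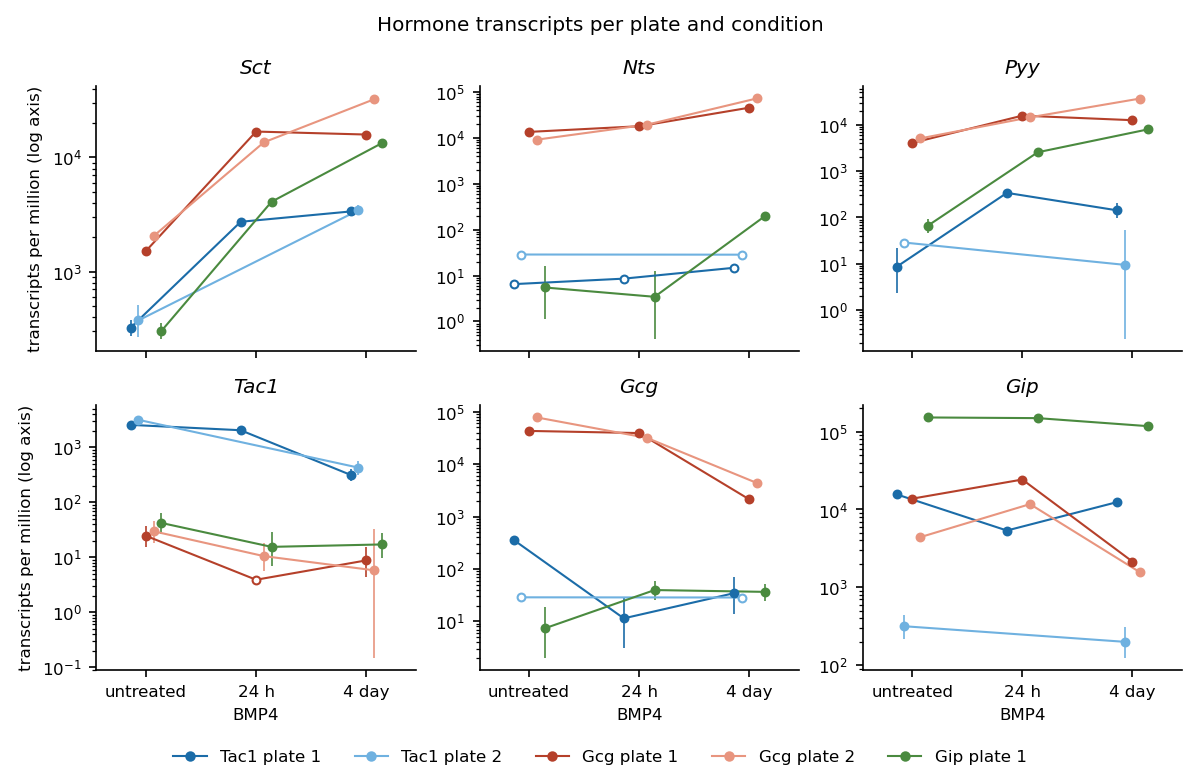
CPM (log axis) of hormone genes in untreated, 24 h and 4 day cells of each of the 5 plates, with exact Poisson 95% intervals that cover counting error only; open points mark 0 transcripts, drawn at the floor of 3 counts. Sct was higher at 4 days than without BMP4 on all 5 plates, and Tac1 lower on both Tac1 plates.

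Of the 12 hormones tested, 3 rose, 2 fell and 7 did not pass (3 higher and 3 lower when adjusted over the list alone). Gcg over all plates was at -2.85 ± 1.00 (adjusted p = 0.18), Gip at -0.74 ± 0.56 (0.59), Cck at -0.71 (0.80) and Sst at -1.14 (0.54). Summing only cells in enteroendocrine clusters, Gcg fell by 3.27 (adjusted p = 0.030; 4.8e-13 to 0.43 over its 18 alternatives) and Sct was at 4.39. Fits of these clusters at 10 cells per sum lack the 4 day sum of Tac1 plate 2, which has too few such cells. Sct was called in each of 18 alternatives, at 3.73 to 4.39. The calls of Pyy, Nts and Tac1 each depended on single plates: without Tac1 plate 1 their adjusted p was 0.058, 0.062 and 0.079, without the Gip plate that of Nts was 0.086 and of Tac1 0.092, without Gcg plate 2 that of Nts was 0.064, and without Tac1 plate 2 that of Tac1 was 0.14. Over 18 alternatives each, the adjusted p ran from 2.1e-24 to 0.058 for Pyy, 3.3e-15 to 0.086 for Nts and 1.7e-10 to 0.34 for Tac1.

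At 4 days 6 of 8 BMP target genes passed, all 6 higher, also when adjusted over the list alone, and the set lay above other genes (camera adjusted p = 1.6e-11; adjusted p = 0.0063 with an estimated correlation). Id1 rose by 5.72 ± 0.34 (adjusted p = 2.1e-07), Id2 by 3.96 ± 0.26 (5.2e-07) and Id3 by 5.05 ± 0.25 (3.0e-08), each on 5 of 5 plates. Smad6 rose by 4.80 ± 0.53 (adjusted p = 1.5e-04), Smad7 by 4.25 ± 0.59 (0.0020) on 4 of 5 plates, and Skil, a repressor of Smad signalling, by 1.82 ± 0.36 (0.010). Skil's adjusted p was 0.097 without Gcg plate 1 and 0.062 without the Gip plate (largest of 18 alternatives, 0.097). Bambi and Tgif1 were at -0.06 and -0.34, and none of the 8 genes for BMP receptors and their Smads passed (camera adjusted p = 0.30).

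The largest other rises that held on 5 of 5 plates were Gsdma, a gasdermin gene with close copies that may share reads, at 4.19 ± 0.36 (adjusted p = 1.1e-05), Sstr1 at 4.03 ± 0.27 (5.2e-07) and Tbx3 at 3.83 ± 0.33 (1.1e-05). Among named genes other than hormones, the largest falls that held on 5 of 5 plates were Spink4, a secreted protease inhibitor, by 3.53 ± 0.56 (adjusted p = 0.0034), Il17re, an interleukin 17 receptor subunit, by 2.81 ± 0.36 (6.3e-04), Nupr1, a stress-induced nuclear protein, by 2.56 ± 0.63 (0.037), Hpd, an enzyme of tyrosine breakdown, by 2.23 ± 0.40 (0.0056), and Fmo1, a flavin monooxygenase, by 2.08 ± 0.32 (0.0033). In total 277 of 8308 genes passed, 200 higher and 77 lower. Over enteroendocrine clusters alone, without a 4 day sum of Tac1 plate 2, 301 passed, 183 higher and 118 lower, and 138 genes were called both times. Without Tac1 plate 1 the count was 90, and without the Gip plate 137. Of the 40 genes named for this comparison that passed, 19 passed whichever plate was left out: Id1, Id2, Id3, Smad6, Smad7, Sct, Iapp, Tbx3, Sstr1, Gsdma, Pcsk1n, Nt5e, Clca1, Nkx2-2, Spink4, Il17re, Hpd, Fmo1 and Gpr56. Of the other 21, leaving out Tac1 plate 1 ended 20 calls (adjusted p from 0.058 to 0.23), the Gip plate 16 (0.056 to 0.25), Tac1 plate 2 10 (0.061 to 0.14), Gcg plate 2 10 (0.052 to 0.24) and Gcg plate 1 4 (0.053 to 0.11).

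**Figure D2:**
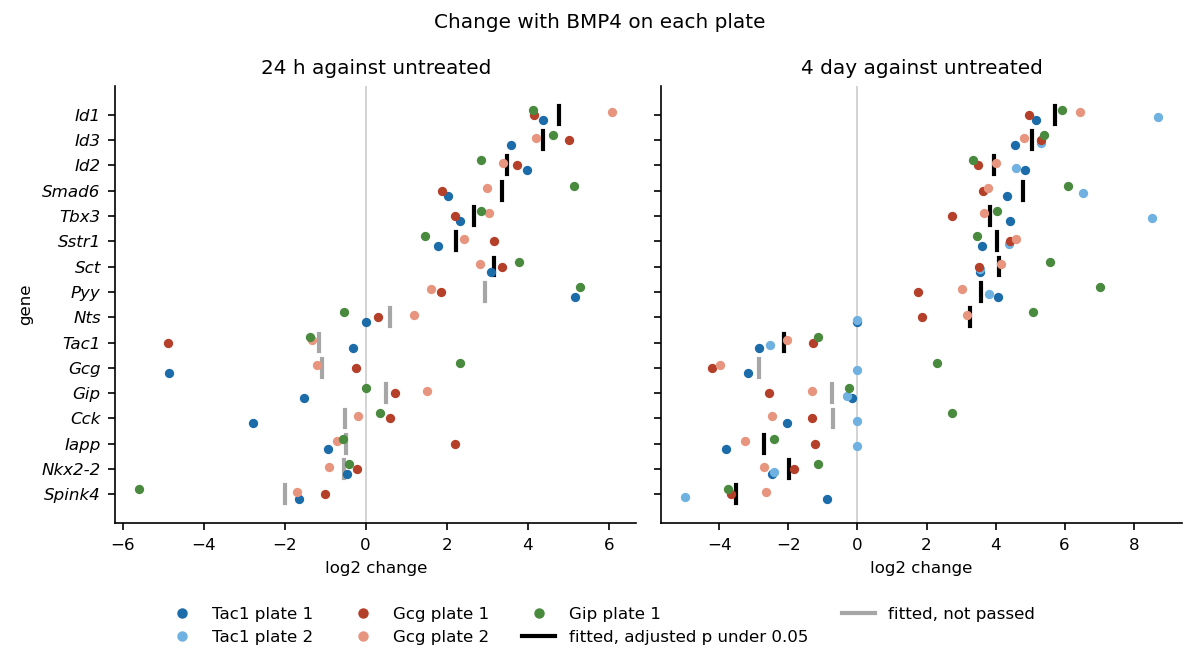
Log2 change in each plate (points) and fitted change (bars, black where the adjusted p was under 0.05 and grey otherwise) of BMP targets, hormones and other named genes after 24 h and after 4 days of BMP4; plates with 0 transcripts in both conditions are drawn at 0. Id1, Id2, Id3 and Sct lay above 0 on every plate drawn.

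Genes of endocrine identity moved both ways. Of 20 enteroendocrine transcription factors, 1 rose and 2 fell (1 higher and 3 lower when adjusted over the list alone), and the set lay below other genes (camera adjusted p = 0.0029; adjusted p = 0.30 with an estimated correlation). Nkx2-2, a homeobox factor of enteroendocrine fate, fell by 1.99 ± 0.23 (adjusted p = 3.3e-04) and Rfx6, a winged-helix factor of the same lineage, by 1.05 ± 0.24 (0.024), while Sox4 rose by 1.52 ± 0.37 (0.037). Over enteroendocrine clusters alone Rfx6 was at -0.66 (adjusted p = 0.075; 6.1e-04 to 0.17 over its 18 alternatives). Of 19 secretory granule genes, Pcsk1n, an inhibitor of prohormone convertase, rose by 2.76 ± 0.31 (adjusted p = 2.0e-04), and Ptprn2 and Pam, the peptide-amidating enzyme, fell by 0.94 ± 0.23 and 0.77 ± 0.19. The other 16 did not pass (2 higher and 4 lower when adjusted over the list alone; camera adjusted p = 0.39). Of 6 serotonin pathway genes, Ddc, the decarboxylase, fell by 0.83 ± 0.19 (adjusted p = 0.022), Tph1 was at 0.71 (0.54), and the set did not pass (1 higher and 1 lower when adjusted over the list alone; camera adjusted p = 0.30). The 7 L, K and I cell genes other than hormones held no call, yet the set lay below other genes (camera adjusted p = 0.014; adjusted p = 0.41 with an estimated correlation).

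Of 5 villus tip genes, Nt5e, which encodes the ectonucleotidase CD73, rose by 2.95 ± 0.41 (adjusted p = 0.0016) and Klf4, a factor of differentiated epithelium, by 2.16 ± 0.46 (0.017). In all 4 rose when adjusted over the list alone (camera adjusted p = 2.6e-04; adjusted p = 0.068 with an estimated correlation). Of 4 crypt and stem cell genes, Smoc2 fell by 2.30 ± 0.50 (adjusted p = 0.019), on 4 of 5 plates (camera adjusted p = 0.014; adjusted p = 0.22 with an estimated correlation). Of 14 enterocyte genes, the apolipoprotein gene Apoc3 rose by 1.48 ± 0.39 (adjusted p = 0.050), and Apoa1, at 2.70 ± 0.74, did not pass (camera adjusted p = 0.24). Enterocyte-like cells made up 4.41% of untreated and 5.64% of 4 day cells on average.

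Goblet cell genes did not move alike: of 8, Clca1 rose by 6.91 ± 0.59 (adjusted p = 8.2e-05; 0.25 with DESeq2, the largest of its 15 alternatives; at 10.44 without Gcg plate 1) on 3 of 5 plates and Zg16, a zymogen granule protein gene, by 3.08 ± 0.66 (0.019; at 2.02 without the Gip plate) on 4 of 5, while Spink4 fell (4 higher and 1 lower when adjusted over the list alone; camera adjusted p = 0.025; adjusted p = 0.30 with an estimated correlation). A few cells carried these transcripts. On Gcg plate 1, 8 goblet-like cells held 96.5% of the 4 day goblet transcripts, on Gcg plate 2, 2 cells held 97.2%, and on the Gip plate 1 cell held 86.9%. Clca1 was not testable in enteroendocrine clusters alone, where Zg16 stood at 2.05.

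Of 11 genes of the unfolded protein response, 2 fell and 9 did not pass (6 lower when adjusted over the list alone; camera adjusted p = 2.1e-05; adjusted p = 0.12 with an estimated correlation). Manf, a secreted stress factor, fell by 0.87 ± 0.19 (adjusted p = 0.020) and Herpud1, a component of protein degradation at the endoplasmic reticulum, by 1.17 ± 0.29 (0.038). Of 10 interferon and antigen presentation genes, Oasl2 rose by 2.63 ± 0.59, Ifit1 by 1.85 ± 0.42 and Irf7 by 1.12 ± 0.29 (adjusted p = 0.021, 0.021 and 0.045). Of the 10, 4 rose when adjusted over the list alone (camera adjusted p = 0.020; adjusted p = 0.12 with an estimated correlation). Of 5 genes of nuclear RNA and RNA quality, Kcnq1ot1, a nuclear antisense RNA, rose by 2.40 ± 0.44 (adjusted p = 0.0073) on 5 of 5 plates, and Malat1 was at 0.25 (camera adjusted p = 0.36). Over the same samples the share of cells in clusters that took no name was 5.72% untreated and 27.1% at 4 days on average, a difference of 21.4 ± 13.3 percentage points (SD, n = 5 plates; exact sign-flip permutation p = 0.0625, two-sided, the smallest that 5 plates allow). Over enteroendocrine clusters alone Kcnq1ot1 was at 0.76 (adjusted p = 0.10; 1.0e-14 to 0.22 over its 18 alternatives). The unnamed clusters hold cells with lower depth, a median of 3687 transcripts against 5940 over all 8 plates. On Tac1 plate 2 it was the other way, 4319 against 3925.

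Other lists gave little. Of 4 proliferation genes, Tyms, a thymidylate synthase gene, rose at 4 days by 1.87 ± 0.41 (adjusted p = 0.019; camera adjusted p = 0.39). Without the unnamed clusters Tyms was at 0.44 (adjusted p = 0.79; 5.0e-06 to 0.79 over its 16 alternatives). No member passed among 9 nutrient and hormone receptors, 10 immediate early and heat shock genes and 10 genes of cholesterol synthesis at 4 days (camera adjusted p = 0.12, 0.98 and 0.49), nor the single tested genes for Wnt targets (Znrf3, -0.34), Paneth cells (Lyz1, -0.68) and tuft cells (Dclk1, 1.74). At 24 h none of the lists named in these sentences, nor those of BMP receptors, transcription factors, granules, serotonin, L, K and I cells, crypt, villus tip, interferon or nuclear RNA genes, held a gene that passed over all genes, and camera's adjusted p for those with at least 2 tested genes ran from 0.13 to 0.94. Adjusted over the list alone, Nt5e of the villus tip list was higher at 1.87 (0.0030) and Pcsk1n of the granule list at 1.18 (0.040).

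The share of cells with secretin transcripts was higher on every plate. With every cell thinned to 2000 transcripts, 14.4% of untreated and 62.1% of 4 day cells held at least 5 Sct transcripts on average, a difference of 47.7 ± 12.0 percentage points (SD, n = 5 plates, higher on 5 of 5; exact sign-flip permutation p = 0.0625, two-sided, the smallest possible). At 24 h the shares were 16.5% and 45.2% over 4 plates, a difference of 28.7 ± 9.62 points (higher on 4 of 4; exact sign-flip permutation p = 0.125, the smallest possible). Without thinning, the untreated and 4 day shares were 10.3% and 63.4% on Tac1 plate 1 and 65.6% and 74.7% on Gcg plate 1. Enterocyte-like cells of the Gcg plates, which should lack secretin, had 0 of 56 cells at this level (Wilson 95% upper bound 6.42%) at a median depth of 17693 transcripts, against 68.4% of 294 enteroendocrine cells there at 9829. Goblet-like cells there went the other way, with 3 of 22 cells at this level (13.6%, Wilson 95% interval 4.75 to 33.3%). Thinning left out 0 untreated cells, 2 at 24 h and 4 at 4 days. The share of cells with at least 5 Tac1 transcripts on Tac1 plate 1 was 48.5% untreated, 32.1% at 24 h and 0 of 41 at 4 days (Wilson 95% upper bound 8.57%). That of Gcg was 68.8%, 72.5% and 30.9% on Gcg plate 1 and 92.0%, 90.4% and 87.5% on Gcg plate 2. Over both Gcg plates and all conditions, 37.5% of enterocyte-like and 54.5% of goblet-like cells reached this level.

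The third comparison, 4 days against 24 h, asks what keeps changing. Of 8308 genes, 33 passed, 25 higher and 8 lower, on 4 plates, and 764 had an unadjusted p under 0.05. Il17re, Fmo1 and Nkx2-2 fell by 2.15 ± 0.39, 2.21 ± 0.33 and 1.45 ± 0.25 (adjusted p = 0.041, 0.015 and 0.026), and the largest fall was that of Iapp, by 2.22 ± 0.42 (0.043). Gsdma rose by 2.76 ± 0.34 (adjusted p = 0.0030), Pcsk1n by 1.58 ± 0.32 (0.047) and Klf4 by 2.48 ± 0.50 (0.048). Sct and Id1 were at 0.92 ± 0.35 (adjusted p = 0.38) and 0.96 (0.13). Of 8 BMP targets none passed over all genes and 5 were higher when adjusted over the list alone. Of 12 hormones 1 was lower (1 higher and 2 lower when adjusted over the list alone). Of 20 transcription factors 1 fell (1 higher and 3 lower over the list alone), of 19 granule genes 1 rose (1 higher and 2 lower) and of 5 villus tip genes 1 rose (4 higher). Over the list alone 1 gene each was also higher among serotonin, proliferation, interferon and nuclear RNA genes, and 1 each lower among serotonin, crypt, unfolded protein response and nuclear RNA genes.

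Goblet genes rose here, 4 of 8 (6 higher and 1 lower when adjusted over the list alone): Zg16 by 4.07 ± 0.67 (adjusted p = 0.026), Clca1 by 4.68 ± 0.49 (0.0030, but 0.69 with DESeq2, and 1.5e-30 to 0.69 over its 15 alternatives), Fcgbp by 3.09 ± 0.45 (0.011) and Muc2 by 2.81 ± 0.48 (0.030). Goblet-like cells were 1.67% of 24 h and 4.37% of 4 day cells on these plates, and over enteroendocrine clusters alone Fcgbp and Muc2 were at 0.85 and 0.34. None of the 17 named calls of this comparison held through all exclusions of a plate: without Tac1 plate 1, 16 ended (adjusted p from 0.10 to 0.43) and 1 gene passed in all. Without the Gip plate 13 ended (0.055 to 0.22) and 4 genes passed. Without Tac1 plate 2, 9 ended (0.054 to 0.094) and 12 genes passed. The totals without Gcg plates 1 and 2 were 120 and 79, with Dbn1 (adjusted p = 0.097), and Iapp and Pcsk1n (0.056 and 0.082), ending. Without the plate as a block, 92 genes passed and Iapp's adjusted p was 0.22.

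Within the Tac1 line, the question is how enterochromaffin cells respond. At 4 days Tac1 itself fell by 2.70 ± 0.54 (SE, n = 2 plates; adjusted p = 0.040) and Sct rose by 3.55 ± 0.46 (0.0086). Pyy rose by 4.20 ± 0.88 (0.046) and Id1 by 5.53 ± 0.58 (0.0086). The rise of Pyy rests on few transcripts: 4 untreated and 29 at 4 days on plate 1, and 0 and 1 on plate 2. At 4 days any Pyy was found in 6 of 41 thinned cells on plate 1 and 1 of 15 on plate 2. Tbx3 rose by 4.85 ± 0.56 (0.0086), S100a10, an annexin partner, by 5.66 ± 0.97 (0.023) and Serpina1e, one of a family of near-identical antitrypsin genes whose reads cannot be parted with certainty, by 6.83 ± 1.00 (0.012). Vim, which encodes vimentin, fell by 3.76 ± 0.44 (0.0086), Irs1, the insulin receptor substrate, by 4.16 ± 0.89 (0.050), Nupr1 by 4.66 ± 0.73 (0.015) and BC048546 by 4.76 ± 0.84 (0.026). Gpr56, an adhesion receptor, went from 119 and 125 CPM to 0 on both plates, where 3 counts would be 14.8 and 28.5 CPM, and the protease gene Prss30 from 0 on both (floors 6.51 and 28.8) to 78.8 and 19.0. The 19.0 on plate 2 lies below the 28.5 of 3 counts, so only plate 1 shows this rise above the floor. In all 167 of 8308 genes passed, 121 higher and 46 lower. Without either Tac1 plate edgeR's test, which then rests on 1 plate assumed to vary like the others, called 0 genes (1139 and 876 had an unadjusted p under 0.05 without plates 1 and 2), and all 13 named calls ended (adjusted p from 0.18 to 0.61 and 0.12 to 0.35). Without plate 1, Id1 went to 10.85, Tbx3 to 10.66 and BC048546 to -9.23, since plate 2 held 0 transcripts of each in one condition. Without plate 2, Irs1 went to -7.61, with 0 at 4 days on plate 1. Without Gcg plate 1 the count was 419. The call of Irs1 also ended without Gcg plate 2 (adjusted p = 0.062), without the Gip plate (0.052) and with DESeq2 (0.093), and that of Tac1 without the Gip plate (0.050). Over their alternatives the adjusted p ran from 5.3e-04 to 0.47 for Irs1 and from 1.4e-14 to 0.51 for Tac1.

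**Figure D3:**
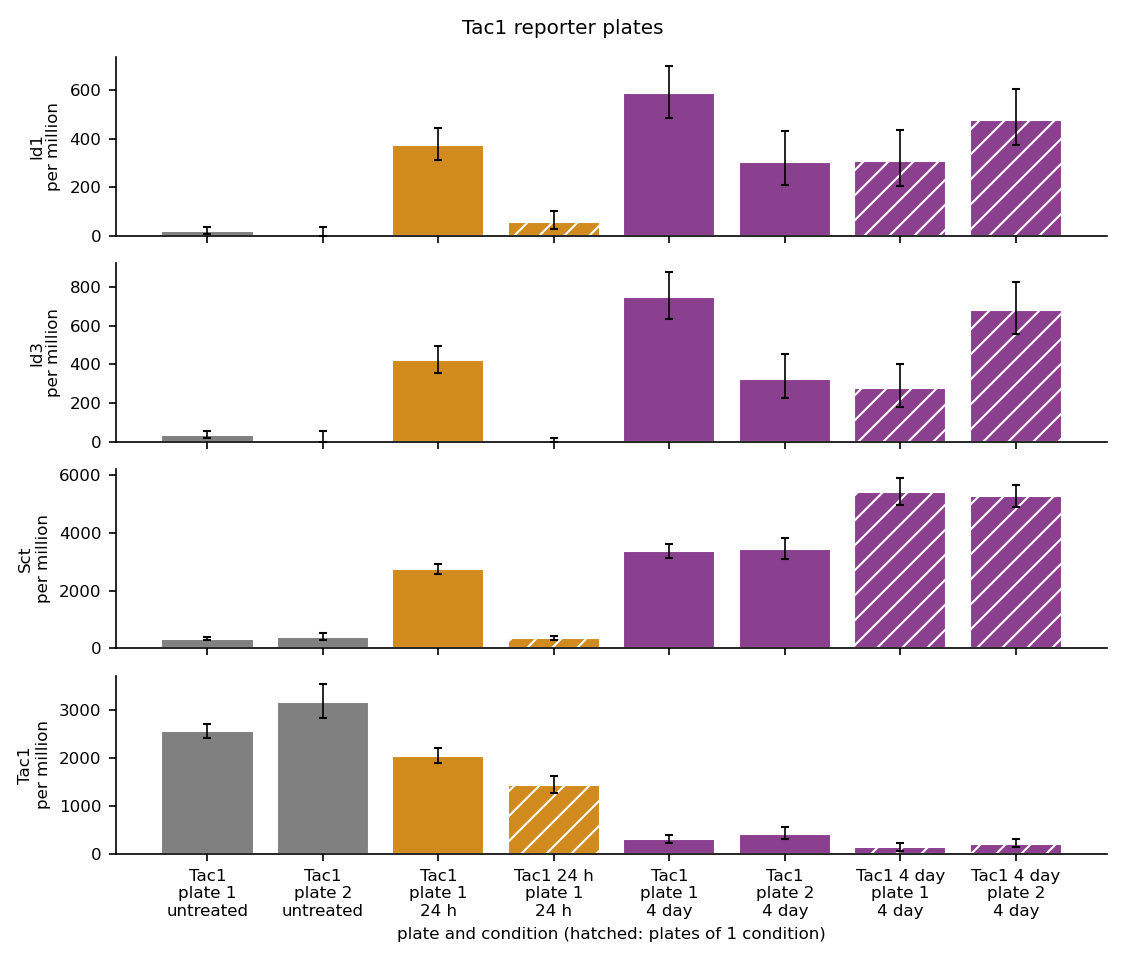
CPM of Id1, Id3, Sct and Tac1 per plate and condition of the Tac1 line (bars, from 0), with exact Poisson 95% intervals for counting error; hatched bars are the plates of a single condition, which enter no test. Sct was at 5431 and 5277 on the plates of 4 days alone and at 343 on the plate of 24 h alone.

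At 24 h the Tac1 line is represented by plate 1 alone, so its SE and p rest on the spread of the other plates and conditions. With that assumed, 2 of 8308 genes passed: Id2 at 3.96 ± 0.47 and Id3 at 3.71 ± 0.45 (both adjusted p = 0.048), with Sct at 3.11 (0.38). Both calls ended without the Gip plate (adjusted p = 0.066 each) and without Tac1 plate 2 (0.50 each), where edgeR called 0 genes (167 and 245 had an unadjusted p under 0.05; with all plates it was 187, and DESeq2 called 6), while 18 and 8 passed without Gcg plates 1 and 2. Id2 ran from 2.4e-12 to 0.89 and Id3 from 9.4e-10 to 1 in adjusted p over 18 alternatives. The upper ends come from the fit of all 5 Tac1 plates, with changes of 3.41 and 3.02, which takes in the plate of 24 h alone, where Sct stood at 343 CPM, near untreated wells.

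Within the Gcg line, the same question concerns L cells. At 4 days Gcg fell by 4.09 ± 0.52 (SE, n = 2 plates; adjusted p = 0.023), from 42919 and 77634 CPM to 2120 and 4350, and Sct rose by 3.86 ± 0.46 (0.012). Nts was at 2.50 ± 0.50 (adjusted p = 0.15), with levels of 13566 and 9186 CPM before and 45782 and 72963 after, and Pyy was at 2.46 (0.10). Id1 rose by 5.68 ± 0.56 (0.0039), Id3 by 5.19 ± 0.40 (0.0019), Sstr1 by 4.60 ± 0.44 (0.0039), Fam101a, an actin regulator, by 4.60 ± 0.51 (0.013) and Clca1 by 6.92 ± 0.71 (0.0085, but 0.9997 with DESeq2, and 1.4e-40 to 0.9997 over its 15 alternatives; at 11.71 without Gcg plate 1), with goblet-like cells at 6.25% and 4.00% before and 8.42% and 8.33% after. Spink4 fell by 3.39 ± 0.48 (0.026), Avpr1b, a vasopressin receptor, by 3.28 ± 0.52 (0.047), Hpd by 2.77 ± 0.44 (0.047) and Nkx2-2 by 2.19 ± 0.36 (0.047). In all 23 genes passed, 16 higher and 7 lower. Over enteroendocrine clusters alone 338 did, among them Gcg at -4.41, Nts at 2.75, Pyy at 2.62, Cck at -1.70 and Gip at -2.70. Gcg's adjusted p was 0.11 and 0.096 without Tac1 plates 1 and 2 and 0.16 without the plate as a block (3.0e-19 to 0.16 over 18 alternatives), and the count was 113, 15, 6 and 8 without Gcg plates 1 and 2 and Tac1 plates 1 and 2. Of the 11 genes named, Id1, Id3 and Sstr1 passed whichever plate was left out. The other 8 lost calls without Tac1 plate 1 (7 of them, adjusted p from 0.055 to 0.14), Tac1 plate 2 (6, 0.074 to 0.13), Gcg plate 2 (3, 0.058 to 0.26), the Gip plate (2, 0.051 to 0.064) and Gcg plate 1 (Hpd, 0.49).

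At 24 h, 6 genes passed on the Gcg plates, 6 higher and 0 lower: Id1 at 5.10 ± 0.55 (adjusted p = 0.0091), Id2 at 3.60 ± 0.35 (0.0044), Id3 at 4.73 ± 0.39 (0.0037), Fam101a at 3.99 ± 0.50 (0.044), Dlk1, a Notch-family ligand, at 5.41 ± 0.46 (0.0044), and Nt5e at 3.08. Sct was at 3.13 ± 0.44 (0.051) and Gcg at -0.67. With equal cell numbers per condition Dlk1 was at 1.02 and 1 gene passed. Without Gcg plates 1 and 2 the count was 22 and 51, and Fam101a's adjusted p was 0.076 and 0.090 without Tac1 plates 1 and 2.

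Whether the lines differ was tested directly, as the Gcg effect minus the Tac1 effect. At 24 h edgeR called 0 of 8308 genes (146 with an unadjusted p under 0.05; DESeq2 called 0), and at 4 days 0 (753 with an unadjusted p under 0.05; DESeq2 called 22). The counts were 6 and 60 without Gcg plate 1, 2 and 2 without Gcg plate 2, and 10 and 90 over enteroendocrine clusters alone. So the hormones that passed in one line and not in the other were not shown to differ by this test. The fit of enteroendocrine clusters alone has only plate 1 on the Tac1 side, since plate 2 has too few such cells at 24 h and 4 days.

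The Gip line has 1 plate and no test. Its values carry counting error only. Gip itself was at 151810 CPM untreated, 148830 at 24 h and 117450 at 4 days, and Sct at 303, 4092 and 13302 (exact Poisson 95% intervals 258 to 353, 3929 to 4260 and 13061 to 13546). Pyy went from 66.0 to 2555 and 7955, Cck from 714 to 897 and 4356, and Sst from 72315 to 77806 and 48783. Id1 stood at 5.50, 108 and 357 CPM (intervals 1.14 to 16.1, 83.3 to 139 and 318 to 398), and Nkx2-2 at 284, 208 and 118. Kcnq1ot1 was at 3983, 11878 and 44692 CPM in the same wells.

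On the mouse assembly GRCm38 (mm10), Sct lies on chromosome 7 from 141278330 to 141279133 on the minus strand, Tac1 on chromosome 6 from 7554879 to 7565834, Gcg on chromosome 2 from 62474530 to 62483650, Gip on chromosome 11 from 96024545 to 96030831, Pyy on chromosome 11 from 102106676 to 102107832 and Nts on chromosome 10 from 102481756 to 102490486. Id1 lies on chromosome 2 from 152736251 to 152737410, Id2 on chromosome 12 from 25093799 to 25097140 and Id3 on chromosome 4 from 136143497 to 136145755. All are protein-coding genes that overlap no other gene of the annotation. Kcnq1ot1, on the minus strand of chromosome 7 from 143203458 to 143296549, overlaps Kcnq1 on the other strand, and Tbx3, Nkx2-2 and Iapp overlap Tbx3os1, Nkx2-2os and Slco1a5. Whether counting used strand is not given in the sources used here, so reads of these pairs are uncertain.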

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

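The tests of explanations and the counts over other splits in this part were chosen only after the results they bear on had been seen. After 4 days of BMP4 Sct rose and Tac1 fell over all plates, and Gcg fell within the Gcg line, while over all plates it did not pass (-2.85, adjusted p = 0.18). Other cell types in the sorted cells are argued against by the enteroendocrine clusters alone, where Sct stood at 4.39, Tac1 at -2.30 and Gcg at -3.27. That fit has no 4 day sum of Tac1 plate 2, which holds too few such cells. Cells of these clusters still changed place by condition: on Tac1 plate 1 a single cluster held 85.3% of untreated and 7.32% of 4 day cells, and on the Gip plate 76.2% and 5.19%. The clusters with the largest 4 day share there were close to these in Tph1 (24.3 against 17.6 per 10000 transcripts) and in Gip (1650 against 1752). Top genes of the first include Gsdma and Sstr1, which rose at 4 days, so this move may restate that change. On Gcg plate 1 a cluster high in Gcg went from 31.25% to 2.11% of cells, and one high in Nts from 10.9% to 34.7%. A shift between enteroendocrine subtypes stays open. A large share of transcripts taken by hormones is argued against, since the change in the share of all other hormones would shift Sct, Tac1 on the Tac1 plates and Gcg on the Gcg plates by at most 0.15 on the log2 scale, either way. Position on the plate follows condition on the 5 plates and cannot be told apart from it. On the 2 Tac1 plates given BMP4 for 4 days throughout, columns 1 to 6, where the other plates hold untreated cells, had 5537 and 1923 CPM of Sct, against 323 and 374 in untreated wells, but in only 2 and 7 cells. On the second of them Sct was at 1923, 3636 and 7716 in columns 1 to 6, 7 to 12 and 13 to 24, and on the first at 5537, 4645 and 5638. No Gcg or Gip plate of that layout was analysed here. A response of enteroendocrine cells to BMP4 stays open beside position and subtype, as a hypothesis found and tested on the same data.

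The Tac1 plate given BMP4 for 24 h throughout showed little of the response. Its 48 cells held 23 transcripts of Id1, Id2 and Id3 together, 118 CPM in 4 cells, against 1365 CPM in 42 of 54 cells at 24 h on Tac1 plate 1. Too few transcripts are argued against, since 267 (exact Poisson 95% interval 236 to 301) would be expected at the level of that plate. A different mix of cells is argued against by cells with at least 5 transcripts of Tac1 and Tph1 together, which held 213 CPM (135 to 319) against 1374. A wrong label or cells that BMP4 did not reach may explain it: Sct stood at 343 CPM (265 to 436), near the 323 and 374 of untreated wells and below the 2734 at 24 h on Tac1 plate 1. The levels of Id1, Id2 and Id3 go both ways here. In untreated wells, cells with at least 5 transcripts of Tac1 and Tph1 together held 83.1 CPM (57.2 to 116.7) on Tac1 plate 1. On Tac1 plate 2 they held 31.2 (6.4 to 91.2), and each level lies below the 213. Yet the 213 comes from 4 of 31 such cells, while 21 of 56 and 2 of 13 untreated ones held any Id1, Id2 or Id3. The Poisson intervals do not cover this spread between cells. Over all cells, untreated wells held 87.7 and 28.3 CPM, with intervals that overlap that of the 118. A wrong label and cells that BMP4 did not reach were not told apart, and no biological explanation was tested.

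Kcnq1ot1 rose on all 5 plates after 4 days, and at 4 days cells of the unnamed clusters held 67.4% (Gcg plate 1) to 94.7% (Tac1 plate 2) of it. It made up 21.9% of their transcripts against 0.411% in enteroendocrine clusters (medians over the 5 plates). Kcnq1ot1 was not kept out of the clustering and is among the top 10 genes of the unnamed cluster of 86 cells. Its concentration there, and its smaller change over enteroendocrine clusters alone, may follow from how the clusters were made. Fewer transcripts per cell are argued against by cells with at least 4000 transcripts, where the change was 2.15. This covers the plates other than Tac1 plate 2, which has too few such cells for a sum. Injured cells with a raised mitochondrial share are argued against on the Tac1 plates, the only 2 of the 5 with mitochondrial genes, where the median share in unnamed clusters was 3.18% and 1.91% against 6.45% and 6.66% in enteroendocrine ones. Loss of cytoplasm with nuclear RNA left would raise Malat1, another nuclear RNA, which stood at a median ratio of 0.546 between the clusters over the plates, from 0.344 on Tac1 plate 2 to 1.11 on the Gip plate, the only plate above 1. Another kind of cell stress and an effect of BMP4 itself stay open as untested.

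Of 64 groups of plates tested for a value far from the rest, 5 had one. Chance alone gives about 1 in 20. Id1 at 24 h changed by 6.09 on Gcg plate 2, against 4.13 to 4.39 on the other plates. Fmo1 at 4 days changed by -3.51 on Tac1 plate 1, against -1.80 on the Gip plate, -1.70 on Gcg plate 2 and -1.44 on Tac1 plate 2, with Gcg plate 1 between these and Tac1 plate 1. Smad7 at 4 days was at 0 on Tac1 plate 2, which held no transcript of it in either condition, against 3.57 to 5.02. Klf4 at 4 days was at 7.62 on Tac1 plate 2, where untreated cells held none, against 1.25 to 3.04. Tmsb4x between 24 h and 4 days changed by 3.71 on Tac1 plate 1, against 1.70 to 1.93.

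By edgeR's test no effect differed between the Gcg and Tac1 lines over all genes (DESeq2 called 0 at 24 h and 22 at 4 days), and those below passed only when adjusted over the list alone. At 24 h the Tac1 side is 1 plate, whose own spread is not measured, so these p-values assume that of the other plates. There the Gcg effect minus the Tac1 effect was 4.25 for Gcg (adjusted p over the list alone 0.021), 2.63 for Gip (0.031), 2.94 for Cck (0.021), -3.54 for Pyy (0.021) and 4.53 for Sst (0.031). It was -2.42 for Tph1 and -3.02 for Lmx1a (both 0.019), and 2.80 for Nt5e (0.0086). At 4 days it was 1.81 for Lmx1a (0.042), 1.64 for Gch1 (0.032), -3.98 for Galr1 (0.040), -3.66 for Sis (0.013) and 2.11 for Neat1 (0.048). Some of the 24 h values rest on few cells. On Tac1 plate 1, at least 5 Gcg transcripts were held by 1 of 68 untreated and 0 of 53 24 h thinned cells. Cck gave the same counts, and Pyy 0 of 68 and 1 of 53. Gip was held by more, 12 of 68 and 8 of 53. On the Gcg plates 7 of 294 enteroendocrine cells held any Tph1.

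The Tac1 plates given BMP4 for 4 days throughout, which enter no comparison, held Sct at 5431 and 5277 CPM, above the untreated wells of both Tac1 plates. Id1 was at 306 and 478 CPM, Id2 at 927 and 1171, and Id3 at 275 and 680, each above the untreated wells.

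Plates pair the conditions, so the genes changed were set against the 16 splits of the sums that part the conditions on every plate, the real split included. These are too few for a share under 0.05. At 24 h the real split gave 8 genes and the highest other 6, and at 4 days 277 and 5, with 1 split, the real one, as high in each. For 4 days against 24 h the real split gave 33 and the highest other 78, and 3 splits gave as many. Over 100 splits, of which the others mix plates and conditions, the highest other gave 11, 185 and 105. Counts of 78 and 105 lie above the real 33, and whether a structure of the samples lies behind this was not tested.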

How the results depend on the processing

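Sums of at least 5 cells, alone or with enteroendocrine clusters, and the exclusion of unnamed clusters were chosen after seeing the data. No call of a named gene reversed. Over all alternatives, named genes kept their side of the threshold in 5514 comparisons, passed newly in 231 and ended in 327. Shares of cells were compared 427 times, but with so few plates the sign-flip test cannot pass, so these comparisons decide nothing. Some differences in shares changed sign. That of enterocyte-like cells ran from -4.05 to 6.10 points for 4 days minus 24 h. Counts of genes, 8 at 24 h, 277 at 4 days and 33 between the times over all plates, moved most, and the cause was not tested unless given. With no expression filter, which tests more genes, they were 46, 653 and 323; for the Tac1 line (2 at 24 h, 167 at 4 days) 16 and 484, for the Gcg line (6 and 23) 22 and 160, and for the difference between lines (0 and 0) 7 and 113. Cells with at least 1000 transcripts gave 138 between the times and 10 in the Gcg line at 24 h. Cells with at least 4000 gave 152 at 4 days, 9 between the times and 7 in the Gcg line at 4 days. Tac1 plate 2 has only 5, 5 and 9 such cells by condition and drops out, so the Tac1 line is plate 1 alone there. Enteroendocrine clusters alone gave 20 at 24 h, 57 between the times, 13 and 275 in the Tac1 line, 60 and 338 in the Gcg line and 10 and 90 for the difference; with sums of at least 5 cells they gave 17, 72, 10 and 262, 22 and 157, and 2 and 71, and 4 lists at 4 days. Sums of at least 5 cells gave 109 between the times. Equal cell numbers, which leave fewer cells, gave 11 between the times, 1 and 103 in the Tac1 line, and 1 and 4 in the Gcg line. Without the unnamed clusters, where the 4 day sum of Tac1 plate 2 has too few cells, 73 passed at 4 days, 8 between the times, 0 and 0 in the Tac1 line (219 and 713 with an unadjusted p under 0.05 in edgeR) and 8 in the Gcg line at 4 days. DESeq2 gave 18 at 24 h, 124 between the times, 6 in the Tac1 line at 24 h, 12 and 44 in the Gcg line and 22 for the difference at 4 days. An estimated correlation left 1 of 4 lists at 24 h and 1 of 8 at 4 days. Size factors by relative log expression, normalisation without hormones and identifiers before the collision correction moved no count by over 1.5 times.

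Fits without the plate as a block gave 9 genes at 24 h, 329 at 4 days, 92 between the times, 3 and 227 in the Tac1 line, 8 and 43 in the Gcg line, 0 and 3 for the difference (0 by edgeR at 24 h, with 182 at an unadjusted p under 0.05), and 4 and 7 lists. Without the block Iapp (adjusted p = 0.060), Apoc3 (0.14) and Zg16 (0.074) ended at 4 days, Iapp (0.22) between the times, Irs1 (0.11) and Pyy (0.097) in the Tac1 line, and Dlk1 (0.35) and Gcg (0.16) in the Gcg line; it changed no other call of a named gene that had passed. All 5 Tac1 plates without the block, which take in the plate of 24 h alone whose treatment is in doubt (118 CPM of Id1, Id2 and Id3 together), gave 0 genes at 24 h (111 with an unadjusted p under 0.05 in edgeR) and 225 at 4 days.

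Leaving out one plate gave 6 to 10 genes at 24 h, 90 to 344 at 4 days (90 without Tac1 plate 1, 137 without the Gip plate) and 1 to 120 between the times (1 without Tac1 plate 1, 4 without the Gip plate, 12 without Tac1 plate 2, 79 and 120 without Gcg plates 2 and 1). In the Tac1 line it gave 0 to 18 and 0 to 419, in the Gcg line 4 to 51 and 6 to 113, for the difference 0 to 6 and 0 to 60, and 2 to 6 and 6 to 8 lists (2 at 24 h without the Gip plate). The difference in the share of unnamed clusters was 17.3 to 25.6 points, and that of cells with at least 5 Sct transcripts 24.1 to 31.0 at 24 h, 43.7 to 51.9 at 4 days and 13.3 to 29.5 between the times.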

Other observations

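The pairs of hormones in single cells below were chosen after seeing the data, with every cell thinned to 2000 transcripts and at least 5 transcripts counted as positive. Intervals are Wilson 95% intervals over cells of 1 plate. On the Gip plate, 0 of 63 untreated Gip-positive cells also held Sct (upper bound 5.75%), 19 of 69 did at 24 h (27.5%, 18.4 to 39.0%) and 85 of 129 at 4 days (65.9%, 57.4 to 73.5%), while 100%, 98.6% and 97.0% of all cells were Gip-positive, a share whose background was not measured. Of Gcg-positive cells, 17 of 44, 38 of 50 and 22 of 29 also held Sct on Gcg plate 1, and 26 of 69, 44 of 75 and 16 of 21 on Gcg plate 2. At 4 days on Gcg plate 1, 29 of 94 cells were Gcg-positive. Over both Gcg plates and all 3 conditions, 21 of 56 enterocyte-like and 12 of 22 goblet-like cells were Gcg-positive. The background at 4 days on Gcg plate 1 alone was not measured, so no excess of the 29 over it was shown. Nts, neurotensin, was found with Gcg in 15 of 44, 20 of 50 and 23 of 29 cells on Gcg plate 1 and in 14 of 69, 33 of 75 and 17 of 21 on Gcg plate 2. Of enterocyte-like cells, pooled in the same way, 10.7% also reached 5 Nts transcripts, and of goblet-like cells 27.3%. Pyy was found with Gcg in 20 of 44, 31 of 50 and 15 of 29 cells on Gcg plate 1. On Gcg plate 2 it was 30 of 69, 37 of 75 and 12 of 21, with intervals that overlap on both plates.

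Cells with Tph1, the first enzyme of serotonin synthesis, were followed on the Tac1 plates. Of Tph1-positive cells on Tac1 plate 1, 12 of 16 untreated, 7 of 14 at 24 h and 0 of 11 at 4 days held Tac1, and 0 of 16, 6 of 14 and 9 of 11 held Sct. On Tac1 plate 2, with few such cells, 0 of 1, 1 of 4 and 1 of 4 held Tac1, and 0 of 1, 2 of 4 and 3 of 4 held Sct. The share of Tph1-positive cells on plate 1 was 23.5%, 26.4% and 26.8%, and on plate 2 it was 1 of 16, 4 of 9 and 4 of 15 cells. On the plates given BMP4 for 4 days throughout, 3 of 6 and 11 of 20 Tph1-positive cells held Sct, and on the plate of 24 h throughout 2 of 12 did.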
